A study of Arabidopsis thaliana with 12 samples.

How the data were processed

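RNA abundance was measured by messenger RNA sequencing of whole Arabidopsis thaliana plants in 12 libraries, 4 genotypes with 3 libraries each. Messenger RNA was isolated with magnetic beads and libraries were made with NEBNext kits, per the labels' protocols, and plants were grown in complete blocks with 3 replications, per the same protocols. The labels did not say whether the replicate numbers in the sample titles are those blocks. Genotype and replicate number of each library were taken from the sample titles.

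The values are raw counts of reads per locus, whole numbers with no normalization, in 1 deposited file per library. Reads were trimmed with Trimmomatic, aligned to TAIR10 with TopHat2 2.0.14 and counted with HTSeq, and DESeq2 was used downstream, per the submitters' processing notes. The strand setting of the counting, the annotation release and the hour of harvest were not given in the sources used here, so counts of overlapping and antisense genes are uncertain. HTSeq leaves out reads that align to more than 1 place, so counts of near-identical gene copies are uncertain too. Of the 28775 loci, 28009 (97.3%) matched a locus tag of the reference annotation, TAIR10.1, which gave symbols, coordinates, exonic length and GC content of the longest transcript. Loci at 0 in all 12 libraries numbered 4849, among them all 133 chloroplast and 146 mitochondrial loci.

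Each file also held 5 rows that name no gene. They took 57.6 to 76.9% of the counts over all rows. As shares of that same total, alignments that were not unique took 54.4 to 73.4%, reads outside genes 1.48 to 3.21% and reads that overlap more than 1 gene 0.346 to 0.852%. These rows were left out of library sizes and tests. Gene counts per library ran from 2820223 to 14277574 (median 6616105), and 19911 to 22117 loci had a count. Reads without molecular identifiers are not independent molecules, so counts near the floor of 3 cover counting error only. For genes with 0 to 3 counts over a group, counts are given in place of fitted changes.

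Counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM factors, filterByExpr (minimum count 10, minimum total count 15), a quasi-likelihood fit with robust estimation and the quasi-likelihood F test. All 12 libraries entered a single fit with genotype as the only term, which left 8 residual degrees of freedom and a common biological coefficient of variation of 0.107, and 17938 genes passed the filter. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called changed. The standard error of a log2 fold change was approximated as its absolute value over the square root of the F statistic. CPM are counts scaled to library size with TMM factors, given as mean and SD over 3 libraries. The comparisons were each of the 3 other genotypes with WT, and GRF1_OE with GRF3_OE. The targeted genes were also tested against the libraries labelled grf123, where edgeR called 3159 genes in GRF1_OE and 2674 in GRF3_OE. The smallest exact two-sided permutation p for 3 against 3 libraries is 0.1, so no permutation test of single genes was run.

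A set of 33 gene lists with 541 genes, 540 of them found among the loci, covered the GRF family, growth, metabolism, hormone and stress responses, the clock, and markers of other organs and of handling. Each list with at least 5 genes past the filter (29 lists; 4 were too small) was tested with camera from limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation, with Benjamini-Hochberg adjustment over the lists of a comparison. List members past the threshold were counted over all genes tested and adjusted over the list alone.

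Named genes followed a rule fixed before the data were examined. It took the GRF family members that passed the filter. Per comparison it took up to 8 genes in each direction with the largest change among called genes with a symbol, no overlap between the libraries of both groups and at least 5 CPM in the higher group. It also took up to 4 called members of each list with a call or with at least 2 members past the threshold, and up to 8 genes per overlap. Not all genes the rule took are written out. CCA1, LHY, PHO2, PHT1;1, GIF1, COPT2 and YSL2 were named after their values were seen. CRU3 was not taken by the rule either, and genes named only through later tests were not chosen by it.

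Overlaps of calls were set beside the number expected for independent lists and beside 20 simulated sets of unchanged groups. In each set all 12 libraries, WT included, were drawn anew from the WT means, gene by gene, with the fitted dispersions. The comparisons of a set shared its simulated WT libraries. Structure of the real WT libraries, such as the distance of WT replicate 3, was not in the simulation. Exonic length and GC content were related to log2 fold changes by Spearman correlation across genes. Alternatives tried were RLE and upper-quartile factors, no count filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, fits of the 6 compared libraries alone, the replicate number as a block, organelle genes left out, an estimated correlation for lists, and leaving out each library in turn. Removal of a loess trend (span 0.5) of log2 CPM with exonic length or with GC content in each library, and leaving out ribosomal RNA genes, were added after the data were seen. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.

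The scripts were tested on simulated counts drawn from the real means and library sizes with genes changed by known folds. In the simulation of GRF1_OE against WT (17599 genes tested), 97.0% of 4-fold, 80.6% of 2-fold and 43.3% of 1.5-fold changes were recovered in the right direction, and 3.05% of calls were false. For GRF3_OE against WT (17551 genes) the values were 97.0, 74.6 and 37.3%, with 5.06% false. For the libraries labelled grf123 against WT (17579 genes) they were 95.5, 77.6 and 23.9%, with 7.33% false, and for GRF1_OE against GRF3_OE (17562 genes) 100, 76.1 and 47.8%, with 7.65% false. Of 30 unchanged simulated lists, 0 were called by camera in any comparison. Genes were drawn independently there, so this does not show how often camera falsely calls lists of correlated genes. A simulated length trend in GRF1_OE against WT (17568 genes) gave 934 false calls before and 0 after removal of the trend. Its Spearman correlation of log2 fold change with exonic length was -0.677, stronger than the -0.379 of the real libraries. No other change was simulated there, so the test does not show how many real changes the removal takes out.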

Results

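The study asked which genes are regulated by GRF1 and GRF3, members of the growth-regulating factor family of plant transcription factors. Transcript counts were given for 12 libraries from whole Arabidopsis thaliana plants of the Ws strain, harvested at 14 days on agar medium. The libraries fell into 4 genotypes with 3 libraries each. These were wild type (WT), plants carrying GRF1-GFP behind the viral 35S promoter (GRF1_OE), plants carrying GRF3-GFP behind the same promoter (GRF3_OE), and plants labelled as mutant in GRF1, GRF2 and GRF3 (labelled grf123 here). Each file listed counts for 28775 loci. Counts assigned to genes were 6010933, 9134491 and 5965816 in GRF1_OE replicates 1, 2 and 3, and 6011082, 6893011 and 8251858 in GRF3_OE. They were 6339199, 3557137 and 14277574 in the libraries labelled grf123, and 8238541, 6893017 and 2820223 in WT. The labels described complete blocks with 3 replications but did not say that the replicates of a genotype came from separate blocks or sowings. The p-values thus measure only the spread between these samples, which may be technical. Sample groups, the tests for changed genes, gene lists and overlaps of the comparisons, the 33 gene lists and the rule for naming genes were fixed before the data were examined, while some other tests and settings were chosen later.

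Library composition differed with genotype. One nuclear 18S ribosomal RNA locus took 13.1 to 19.4% of gene counts in the overexpressors, 21.6 to 24.4% in the libraries labelled grf123 and 18 to 31.8% in WT. Unique reads outside genes made up 4.08 to 4.66% in GRF1_OE, 4.57 to 5.11% in GRF3_OE, 6.39 to 9.53% in the libraries labelled grf123 and 8.28 to 12.1% in WT. WT replicate 3 had the lowest depth and the highest share of both. It also stood apart on the first principal components of log2 counts scaled to library size, which took 31.5% and 20.9% of the variance, at 55.1 and 43.7 against 20.01 and 0.389 or 22.5 and 9.37 for the other WT libraries. Pearson correlations of replicate pairs were 0.958 to 0.982 in WT, 0.980 to 0.987 in GRF1_OE, 0.982 to 0.983 in GRF3_OE and 0.975 to 0.979 in the libraries labelled grf123. No pair of replicates agreed within sampling noise.

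The targeted genes were examined first. GRF1 (AT2G22840) lies on the plus strand of chromosome 2 from 9728480 to 9731301 in TAIR10.1, GRF2 (AT4G37740) on the minus strand of chromosome 4 from 17725337 to 17727909, and GRF3 (AT2G36400) on the minus strand of chromosome 2 from 15270088 to 15273115. The longest transcript of each has 4 exons, with exonic lengths of 2114, 2104 and 1907 bp, and reads over exons were counted for the whole gene. GRF1 stood at 17.1 ± 1.57 library-scaled counts (CPM; SD, n = 3) in WT and 149.9 ± 35.0 in GRF1_OE, where it rose by 3.16 (log2, SE 0.15, edgeR adjusted p = 9.7e-12). GRF3 stood at 22.5 ± 6.78 CPM in WT and 209.9 ± 13.7 in GRF3_OE, a log2 change of 3.31 (SE 0.15, edgeR adjusted p = 8.83e-12). These counts did not separate transgene from endogenous transcripts.

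In the libraries labelled grf123, GRF2 fell from 11.1 ± 2.35 to 0.929 ± 0.253 CPM (SD, n = 3). That was a log2 change of -3.73 (SE 0.36, edgeR adjusted p = 5.34e-07). GRF1 fell to 8.58 ± 1.25 CPM, a log2 change of -0.91 (SE 0.18, edgeR adjusted p = 0.00396). GRF3 stood at 22.7 ± 2.62 CPM, against 22.5 in WT, and did not pass the test (log2 change 0.08, SE 0.16, edgeR adjusted p = 0.848). The GRF3 level thus went against the label as far as whole-gene counts show it, and directions drawn from these libraries rest on the label. Insertion sites were not given in the sources used here, so a count over the whole gene does not show whether an intact transcript was made.

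GRF2 was also low in both overexpressors. Its CPM was 0.742 ± 0.493 in GRF1_OE and 0.869 ± 0.275 in GRF3_OE, from 8, 3 and 4 counts and 6, 8 and 5 counts, against 98, 85 and 19 counts in WT. The log2 changes were -4.03 (SE 0.36) and -3.72 (SE 0.35), with edgeR adjusted p = 4.44e-08 and 5.67e-07, and DESeq2 gave no adjusted p for the second. GRF1 in GRF3_OE stood at 8.85 ± 0.153 CPM and fell by 0.92 on the log2 scale (SE 0.18, edgeR adjusted p = 0.0026). Set directly against the libraries labelled grf123, GRF1 in GRF3_OE differed by -0.01 (log2, SE 0.19, edgeR adjusted p = 0.978). GRF2 differed by -0.30 (SE 0.52, edgeR adjusted p = 0.742) in GRF1_OE and 0.01 (SE 0.48, edgeR adjusted p = 0.996) in GRF3_OE. Of the other family members, GRF4, GRF5, GRF8 and GRF9 passed the count filter and none of these passed the test in any genotype against WT. The family as a list was called in the libraries labelled grf123 (0 of 7 rose and 2 fell, likewise adjusted over the list alone; camera adjusted p = 0.0107), where its median was 0.08, its mean -0.63 and the test direction down. The 2 that fell were GRF1 and GRF2, which the label names as mutated, so the call says nothing of the rest of the family. Its adjusted p = 0.113 with an estimated correlation, and the call was lost without grf123 replicate 1 (camera adjusted p = 0.14) or WT replicate 1 (camera adjusted p = 0.0993), and with no filter on low counts (camera adjusted p = 0.169). The median was -0.15 and -0.13 without WT replicates 1 and 2, 0.21 and 0.18 without grf123 replicate 3 and WT replicate 3, and 0.01 without grf123 replicate 1.

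**Figure D1:**
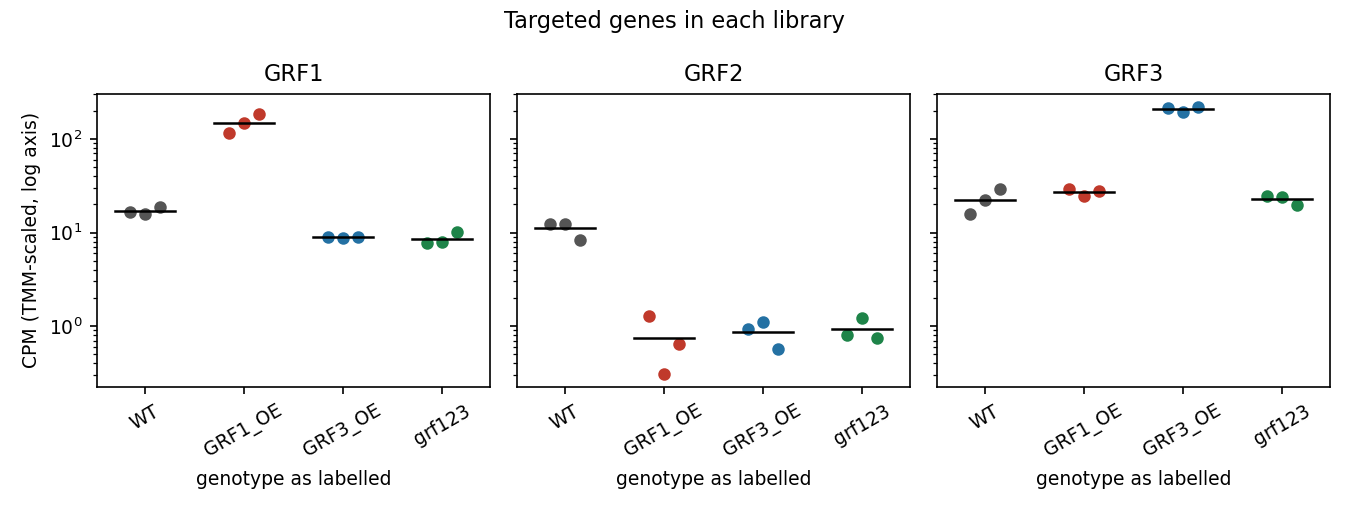
CPM of GRF1, GRF2 and GRF3 (TMM-scaled, log axis) in each library by labelled genotype, with points for the 3 libraries of a genotype and a black line at their mean. GRF1 is highest in GRF1_OE (mean 149.9), GRF3 is highest in GRF3_OE (mean 209.9), and GRF2 is below 1 CPM on average in each genotype other than WT.

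The comparison of GRF1_OE with WT asked which transcripts differ in plants that express GRF1 from the 35S promoter. GRF2 was at 0.742 CPM in these plants and 11.1 in WT, so the comparison does not separate high GRF1 from low GRF2. Besides GRF1, the 7 largest increases among genes named by rule were in COR27, JMJD5, ELF4, GRP7, TH8, NATA1 and COL9. COR27, a cold-regulated and clock-controlled gene, rose from 0.425 CPM (2, 4 and 1 counts) to 16.2 CPM (89, 169 and 107 counts), a log2 change of 5.24 (SE 0.33, n = 3). JMJD5, a histone demethylase gene with evening expression, rose by 4.26 (SE 0.30), ELF4, a component of the evening complex of the clock, by 3.14 (SE 0.20), and GRP7, a clock-controlled RNA-binding protein gene, by 3.13 (SE 0.14) from 110 to 971 CPM. TH8, a thioredoxin gene, rose by 2.94 (SE 0.55), NATA1, an ornithine acetyltransferase gene, by 2.74 (SE 0.50) and COL9 by 2.67 (SE 0.22). The 8 largest decreases were in LEA7, the seed storage gene CRU1, RD29B, GRF2, HSFA6A, LEA4-5, TSPO and RAB18. LEA7, a late embryogenesis abundant protein gene, fell from 160 to 1.84 CPM (log2 change -6.56, SE 0.87), and the log2 changes were -5.28 (SE 0.71) for RD29B, -3.79 (SE 0.33) for LEA4-5 and -3.28 (SE 0.49) for the dehydrin gene RAB18. HSFA6A, a heat shock factor gene, had -3.81 (SE 0.54) and TSPO -3.55 (SE 0.60). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 3911 of 17938 genes changed, 1794 higher and 2117 lower. Of these, 298 were at least 2-fold higher and 331 at least 2-fold lower. Which direction held the majority turned with upper-quartile factors, where 2151 were higher and 1768 lower. The count was 2494 without GRF1_OE replicate 1 and 3265 without WT replicate 3, the library that stood apart. A trend with transcript length is described further on, and 2519 genes were called after its removal.

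**Figure D2:**
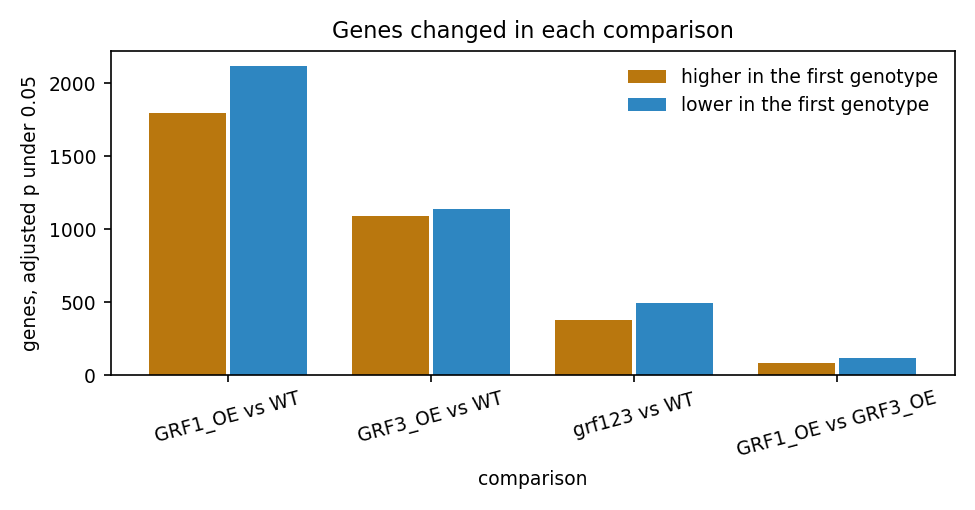
Number of genes with an edgeR adjusted p under 0.05 in each comparison, drawn as bars for genes higher and lower in the first-named genotype. GRF1_OE against WT gave 1794 higher and 2117 lower genes, and the direct comparison of the overexpressors gave 87 and 117.

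Of 29 measured genes on the fixed list for abscisic acid, drought and cold, 1 rose and 18 fell in GRF1_OE (adjusted over the list alone, 1 and 19), with a median log2 change of -1.08 (camera adjusted p = 3.56e-18, and adjusted p = 0.359 with an estimated correlation). Besides RD29B, RAB18 and LEA7, LTP4, a lipid transfer protein gene, fell by 2.75 on the log2 scale (SE 0.47). Of 21 heat shock genes, 1 rose and 10 fell (adjusted over the list alone, 1 and 13), with a median of -1.03 (camera adjusted p = 1.55e-06, and adjusted p = 0.436 with an estimated correlation). The chaperone gene HSP70-4 fell from 168 to 56.6 CPM (log2 change -1.58, SE 0.37). With the length trend removed, the medians of these lists were -1.1 and -1.05, and without WT replicate 3 they were -0.92 and -0.98. Without GRF1_OE replicate 1, 0 heat shock genes rose and 15 fell. Seed storage markers moved with the abscisic acid list. Their 2 measured members, too few for the list test, had lower counts in both overexpressors, and adjusted over the list alone both fell. CRU1, a cruciferin gene, had 7, 95 and 17 counts in the WT libraries, 0, 2 and 0 in GRF1_OE, 0, 1 and 0 in GRF3_OE, and 1, 15 and 126 in those labelled grf123. Its edgeR adjusted p was 0.0487 in GRF1_OE, and that call was lost without GRF1_OE replicate 1 (0.132), 2 (0.15) or 3 (0.116) or WT replicate 2 (0.185) or 3 (0.0859), and with the length (0.0631) or GC trend removed (0.0543).

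The clock list held 21 measured genes, of which 9 rose and 9 fell in GRF1_OE (adjusted over the list alone, 10 and 10). Its median was -0.01, its mean 0.37 and the test direction up (camera adjusted p = 0.00212, and adjusted p = 0.436 with an estimated correlation), and the call was lost with no filter on low counts (camera adjusted p = 0.0753). Without single libraries the median lay between -0.07 (WT replicate 3) and 0.10 (WT replicate 2). FKF1, an evening-expressed blue-light receptor gene, rose by 2.45 (log2, SE 0.19) and PRR3 by 2.25 (SE 0.16). Sorted by known phase after the values were seen, 8 of 9 evening genes rose and 0 fell, while 0 of 11 morning genes rose and 9 fell. CCA1 and LHY, the MYB genes of the morning loop, were named after their values were seen. They fell by 0.92 (SE 0.14, edgeR adjusted p = 0.000173) and 1.42 (SE 0.20, edgeR adjusted p = 0.000231) on the log2 scale. Without each library in turn the edgeR adjusted p was 1.56e-05 to 0.00202 for CCA1 and 7.15e-06 to 0.00392 for LHY. The hour of harvest of each genotype was not given in the sources used here. In GRF3_OE, 4 evening genes rose and 0 fell and 0 morning genes rose and 2 fell. In the libraries labelled grf123 the numbers were 0 and 0, and 1 and 0.

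**Figure D3:**
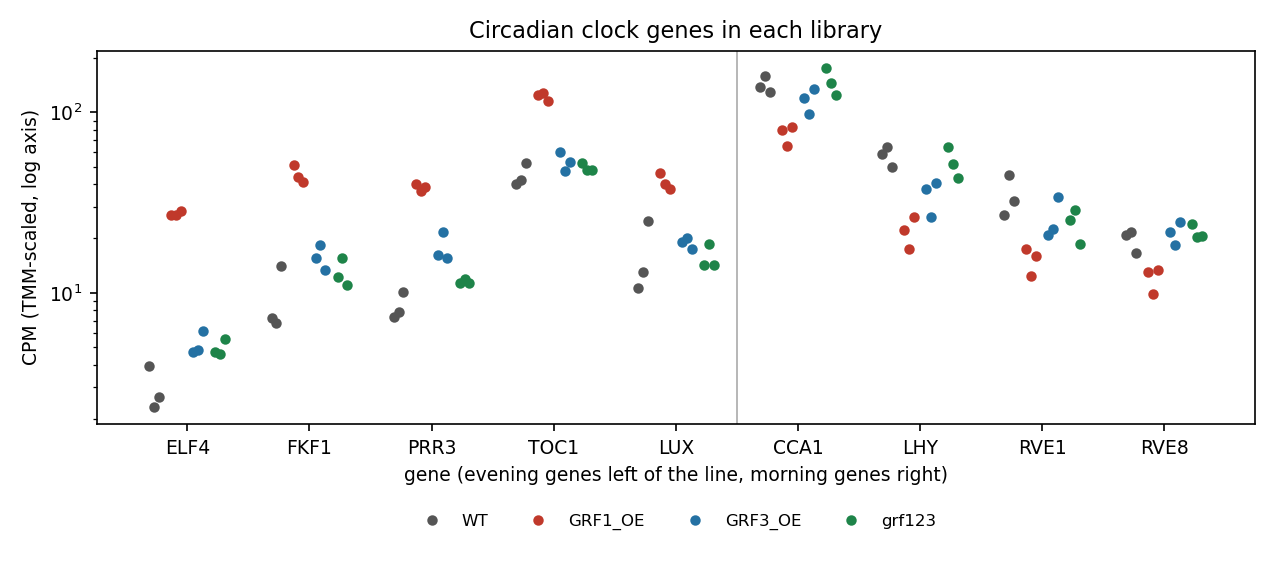
CPM (TMM-scaled, log axis) of 9 circadian clock genes in each library, coloured by labelled genotype, with evening genes left of the line and morning genes right of it. ELF4 averages 27.4 CPM in GRF1_OE and 2.97 in WT, and LHY is lower in GRF1_OE than in WT by 1.42 on the log2 scale (log2 change -1.42).

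Genes of chlorophyll synthesis were lower in GRF1_OE, with 0 of 17 rising and 5 falling (adjusted over the list alone, 2 and 8) and a median of -0.17 (camera adjusted p = 0.00372, and adjusted p = 0.436 with an estimated correlation). HEMA1, which encodes the first committed enzyme of tetrapyrrole synthesis, fell from 406 to 126 CPM (log2 change -1.68, SE 0.12), and CHLH, a magnesium chelatase subunit gene, by 0.98 on the log2 scale (SE 0.12). The iron deficiency list was called higher, with 3 of 19 rising and 0 falling (adjusted over the list alone, 7 and 0), a median of 0.86 and NAS4, a nicotianamine synthase gene, up by 1.13 (SE 0.21; camera adjusted p = 1.08e-05, and adjusted p = 0.436 with an estimated correlation). NAS3, another gene of that family, fell by 2.58 on the log2 scale (SE 0.30). Of 9 root markers, 0 rose and 6 fell (adjusted over the list alone, 0 and 6), with a median of -1.40, among them the root hair gene PRP3 by 2.08 on the log2 scale (SE 0.31; camera adjusted p = 0.00182, and adjusted p = 0.436 with an estimated correlation). Without single libraries these counts moved. Iron deficiency had 1 rising without GRF1_OE replicate 1 or 3 or WT replicate 1 or 2, and chlorophyll synthesis 1 rising without GRF1_OE replicate 1 or WT replicate 3. The chlorophyll median was -0.11 without GRF1_OE replicate 1 and -0.06 without WT replicate 2. Root markers had 2 falling without WT replicate 1, and their median was -0.91 without it and -0.87 without WT replicate 3. A floral organ gene, PI, rose by 2.04 (SE 0.31) from 1.91 to 8.39 CPM.

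Another 6 lists were called in GRF1_OE. Jasmonate and ethylene defence genes (3 of 7 rose, 0 fell; adjusted over the list alone, 3 and 0; camera adjusted p = 0.0176) included PR4, which rose by 1.41 (SE 0.15), and aliphatic glucosinolate genes (3 of 19 rose, 0 fell; adjusted over the list alone, 3 and 0; camera adjusted p = 0.0182) were higher. Expansins and xyloglucan-modifying XTH genes (0 of 22 rose, 3 fell; adjusted over the list alone, 0 and 3; camera adjusted p = 0.00969) included XTH17, which fell by 1.60 on the log2 scale (SE 0.35). Auxin response genes (0 of 14 rose, 6 fell; adjusted over the list alone, 0 and 6; camera adjusted p = 0.0133), xylem markers (0 of 8 rose, 3 fell; adjusted over the list alone, 0 and 5; camera adjusted p = 0.00969) and touch and wound genes (0 of 13 rose, 2 fell; adjusted over the list alone, 0 and 2; camera adjusted p = 0.00185) were lower. With an estimated correlation the adjusted p = 0.436 for jasmonate and ethylene defence, expansins, auxin and xylem, 0.586 for glucosinolates and 0.572 for touch and wound. Single libraries ended 4 of these calls. They were glucosinolates without GRF1_OE replicate 3 (camera adjusted p = 0.0656) or WT replicate 2 (0.0878), auxin (0.0543) and touch and wound (0.0863) without WT replicate 3, and xylem without GRF1_OE replicate 1 (0.0734). Counts past the threshold moved too. Jasmonate and ethylene defence had 1 rising without GRF1_OE replicate 1 or 3 or WT replicate 2 or 3. Glucosinolates had 1 rising without GRF1_OE replicate 2, 0 without GRF1_OE replicate 3 or WT replicate 2, and 6 without WT replicate 1. Expansins had 5 falling without WT replicate 1 or 3, auxin 3 without GRF1_OE replicate 2 or 3 or WT replicate 2, and xylem 1 without GRF1_OE replicate 1. Touch and wound had 0 falling without GRF1_OE replicate 1, 1 without GRF1_OE replicate 2 or 3 or WT replicate 2, and 6 without WT replicate 1. The jasmonate and ethylene call was lost with the length trend removed (camera adjusted p = 0.0816). Of 29 lists tested, 12 were called, 4 higher and 8 lower, and 0 by camera with an estimated correlation, where 2 had an unadjusted p under 0.05. Mitotic cell cycle genes were not called, with 0 of 19 past the threshold, likewise adjusted over the list alone (camera adjusted p = 0.649, and adjusted p = 0.81 with an estimated correlation).

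The comparison of GRF3_OE with WT asked the same of GRF3. Here GRF2 was low too, and GRF1 was at 8.85 against 17.1 CPM in WT, so high GRF3 is not separated from these decreases. NATA1 rose from 2.51 to 13.0 CPM (log2 change 2.66, SE 0.50, n = 3), BAM5, a beta-amylase gene, from 22.9 to 91.2 CPM (log2 change 1.95, SE 0.20), and IPS1, a noncoding RNA gene of phosphate starvation, from 4.28 to 12.7 CPM (log2 change 1.65, SE 0.27). The pathogenesis-related gene PR1 had a log2 change of 3.5 (SE 0.82, edgeR adjusted p = 0.0294). That call was lost without GRF3_OE replicate 2 (0.0751) or 3 (0.0793) or WT replicate 1 (0.092), 2 (0.104) or 3 (0.0589), and with the length trend removed (0.0593), by edgeR adjusted p. LEA7 fell from 160 to 9.17 CPM (log2 change -4.0, SE 0.67), and the log2 changes were -3.6 (SE 0.59) for RD29B, -2.57 (SE 0.29) for LEA4-5 and -2.41 (SE 0.46) for RAB18. Fitted to the 6 compared libraries alone, LEA7 (edgeR adjusted p = 0.0538) and RAB18 (0.0791) no longer passed. In all, edgeR's test called 2226 of 17938 genes, 1088 higher and 1138 lower, of which 114 and 159 differed at least 2-fold. The count fell to 1200 without GRF3_OE replicate 2, 1240 without GRF3_OE replicate 3 and 1309 without WT replicate 2, and was 1550 without WT replicate 3. It was 963 with the length trend removed, 566 higher and 397 lower. More genes were higher than lower also with upper-quartile factors (1178 and 1087) and without GRF3_OE replicate 1 (759 and 736) or 2 (607 and 593).

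Abscisic acid, drought and cold genes were lower in GRF3_OE as well, with 1 of 29 rising and 14 falling (adjusted over the list alone, 1 and 18) and a median of -0.58 (camera adjusted p = 3.55e-17, and adjusted p = 0.426 with an estimated correlation). The seed storage gene CRU1 was at 0, 1 and 0 counts in GRF3_OE and 7, 95 and 17 in WT. Without GRF3_OE replicate 1, 2 or 3 or WT replicate 1 or 2, 0 genes of the abscisic acid list rose by edgeR's test. Phosphate starvation genes were higher, with 8 of 15 rising and 1 falling (adjusted over the list alone, 10 and 1) and a median of 0.68 (camera adjusted p = 2.71e-05, and adjusted p = 0.475 with an estimated correlation). The gene that fell was the phosphate transporter gene PHT1;1 (log2 change -0.70, SE 0.20, edgeR adjusted p = 0.0255), named after its value was seen. Without GRF3_OE replicate 1 or 3 or WT replicate 2 or 3 it did not pass, and over all single libraries left out its edgeR adjusted p was 0.0135 to 0.11. Nor did it pass with the length trend removed (edgeR adjusted p = 0.0553). PECP1, a phosphatase gene, had a log2 change of 1.05 (SE 0.29, edgeR adjusted p = 0.0202). Its call was lost without GRF3_OE replicate 1 (edgeR adjusted p = 0.0669) or 3 (0.0843) or WT replicate 2 (0.103), and with the length trend removed (0.0725). With the length trend removed the medians were -0.62 for the first list and 0.61 for the second, and without WT replicate 3 they were -0.62 and 0.65. Removal of the length trend left 5 phosphate genes rising and 0 falling, and 0 abscisic acid genes rising and 14 falling. The phosphate list had 3 rising and 0 falling without GRF3_OE replicate 3 (median 0.43), 5 and 1 without WT replicate 1, 5 and 0 without WT replicate 3, and 6 and 0 without GRF3_OE replicate 1 or WT replicate 2.

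Another 8 lists were called in GRF3_OE. Jasmonate and ethylene defence genes (2 of 7 rose, 0 fell; adjusted over the list alone, 2 and 0; camera adjusted p = 0.0204) included PR4, up by 1.1 (SE 0.15), and cytokinin genes (1 of 10 rose, 0 fell; adjusted over the list alone, 2 and 0; camera adjusted p = 0.026) included the response regulator gene ARR4, up by 0.56 (SE 0.11). Iron deficiency genes (1 of 19 rose, 0 fell; camera adjusted p = 0.0227) were higher. Heat shock genes (0 of 21 rose, 2 fell), touch and wound genes (0 of 13 rose, 0 fell), root markers (0 of 9 rose, 2 fell) and auxin response genes (0 of 14 rose, 3 fell) were lower, each with camera adjusted p = 0.0227, as were xylem markers (0 of 8 rose, 1 fell; camera adjusted p = 0.0394). Adjusted over the list alone, the numbers past the threshold in these 6 lists were the same. With an estimated correlation the camera adjusted p of all 8 lists was 0.475 to 0.718. Each of these 8 calls was lost without 1 or more of GRF3_OE replicates 1, 2 and 3 and WT replicates 1 and 3, with camera adjusted p of 0.0563 to 0.975 in those fits, and touch and wound turned upward without WT replicate 3. With the GC trend removed the cytokinin (0.105) and xylem (0.069) calls were lost, the second also with no filter on low counts (0.0823), by camera adjusted p. Without WT replicate 3 the counts past the threshold were 0 for iron, heat shock, auxin and xylem, 1 for jasmonate and ethylene defence and 2 for cytokinin. Iron had 0 also without GRF3_OE replicate 3 or WT replicate 1 or 2, and jasmonate and ethylene defence 1 without WT replicate 1 or 2. Heat shock had 0 falling without GRF3_OE replicate 2 and 1 without GRF3_OE replicate 1 or WT replicate 2. Auxin had 0 falling without GRF3_OE replicate 2 or 3 or WT replicate 2, where 1 rose in the last, and xylem 0 without GRF3_OE replicate 1 or 2. Root markers had 4 falling without GRF3_OE replicate 1, 0 without GRF3_OE replicate 2 or 3 or WT replicate 1, and 1 without WT replicate 2. Cytokinin had 3 rising without GRF3_OE replicate 3 and 2 without WT replicate 1, where 1 fell, and touch and wound had 2 falling without WT replicate 1. In total 10 of 29 lists were called, 4 higher and 6 lower, and 5 without GRF3_OE replicate 1 or 2, while 17 were called with the length trend removed. With an estimated correlation camera called 0, and 3 had an unadjusted p under 0.05.

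The libraries labelled grf123, in which GRF2 was near 0, GRF1 was at 8.58 against 17.1 CPM and GRF3 was at the WT level, were compared with WT. Copper and zinc superoxide dismutase genes and their chaperone gene were among the 8 largest increases named by rule. CSD2 rose from 28.2 to 161 CPM (log2 change 2.48, SE 0.22, n = 3), CSD1 by 1.90 (SE 0.16) and CCS, the copper chaperone gene of these enzymes, by 1.78 (SE 0.19). NATA1 (log2 change 2.28, SE 0.52, edgeR adjusted p = 0.0304) and PDF2.1, a defensin-like gene (log2 change 1.96, SE 0.42, edgeR adjusted p = 0.00894), ranked between CSD2 and CSD1. NATA1 did not pass without grf123 replicate 2 (edgeR adjusted p = 0.07) or 3 (0.146) or WT replicate 1 (0.0783) or 2 (0.088), nor PDF2.1 without grf123 replicate 3 (0.102) or WT replicate 1 (0.0588) or 2 (0.0814). FSD1, an iron superoxide dismutase gene, fell from 612 to 204 CPM (log2 change -1.58, SE 0.24, edgeR adjusted p = 0.00469), and in a fit of the 6 compared libraries alone it did not pass (0.0688). The 8 largest decreases were in EXT12, GRF2, EXT13, RHS19, XTH14, LEA7, CYP71B22 and EXT10. The extensin genes EXT12, EXT13 and EXT10 had log2 changes of -3.75 (SE 0.37), -3.72 (SE 0.41) and -2.79 (SE 0.46), RHS19 of -3.34 (SE 0.44) and XTH14 of -3.27 (SE 0.40). LEA7 had -3.16 (SE 0.63, edgeR adjusted p = 0.0287) and CYP71B22, a cytochrome P450 gene, -2.91 (SE 0.41). LEA7 did not pass without grf123 replicate 1 (edgeR adjusted p = 0.076), 2 (0.0872) or 3 (0.112) or WT replicate 2 (0.0696) or 3 (0.0591). Extensins hold repeated sequence, so their unique counts are uncertain. By edgeR's test 875 of 17938 genes changed, 378 higher and 497 lower, of which 119 and 200 differed at least 2-fold. The count was 377 without grf123 replicate 3, the deepest library, 479 without WT replicate 2 and 683 without WT replicate 3. It was 535 in a fit of the 6 compared libraries alone.

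Aliphatic glucosinolate genes, which make methionine-derived defence compounds, were higher in the libraries labelled grf123, with 14 of 19 rising and 0 falling (adjusted over the list alone, 16 and 0) and a median of 0.68 (camera adjusted p = 9.22e-19, and adjusted p = 0.0912 with an estimated correlation). MYB29, a transcriptional activator of the pathway, rose by 1.13 (SE 0.18) from 11.3 to 24.5 CPM, CYP79F1 by 0.81 (SE 0.14) and BCAT4 by 0.77 (SE 0.12). Phosphate starvation genes were lower, with 1 of 15 rising and 10 falling (adjusted over the list alone, 1 and 12) and a median of -1.02 (camera adjusted p = 7.01e-11, and adjusted p = 0.0912 with an estimated correlation). PHO2, a repressor of phosphate uptake, was the member that rose (log2 change 0.78, SE 0.09, edgeR adjusted p = 1.4e-05), named after its value was seen. PECP1 and IPS1 fell by 2.26 (SE 0.41, edgeR adjusted p = 0.00141) and 1.72 (SE 0.38, edgeR adjusted p = 0.00852) on the log2 scale, and both calls were lost without grf123 replicate 3, with edgeR adjusted p = 0.0517 and 0.119. Glucosinolates had 7 rising without grf123 replicate 3 or WT replicate 2 and 8 without grf123 replicate 2. The phosphate list had 3 falling without grf123 replicate 3 and 6 without WT replicate 2.

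**Figure D4:**
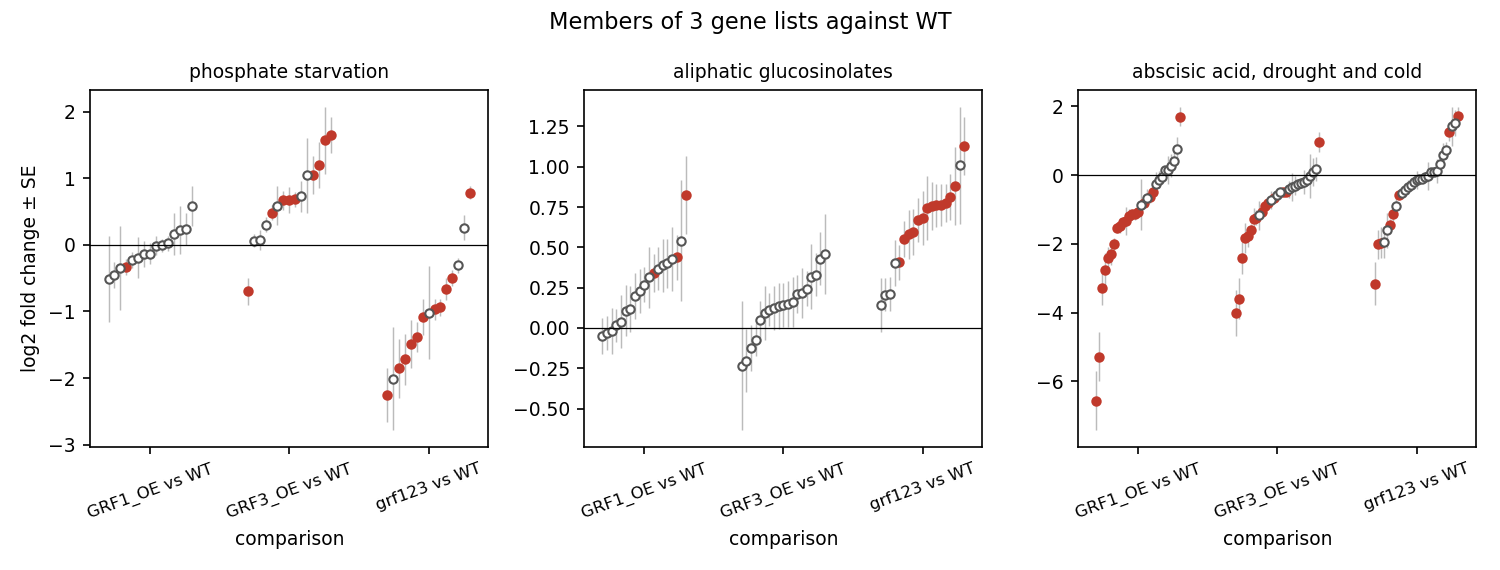
Log2 fold change against WT (y axis, bars are SE) of each measured member of 3 fixed gene lists, ordered by value within each comparison, with filled points past the threshold and open points not. Phosphate starvation genes lie mostly above 0 in GRF3_OE (median 0.68) and below 0 in the libraries labelled grf123 (median -1.02), and abscisic acid, drought and cold genes lie lowest in GRF1_OE (median -1.08).

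Stress and wall lists moved as well in the libraries labelled grf123. Touch and wound genes were lower (0 of 13 rose, 4 fell; adjusted over the list alone, 0 and 8; median -1.24; camera adjusted p = 5.57e-11, and adjusted p = 0.19 with an estimated correlation), and TCH2, a calmodulin-like gene, fell by 1.02 on the log2 scale (SE 0.22). Heat shock genes were lower (0 of 21 rose, 5 fell; adjusted over the list alone, 0 and 10; median -0.76; camera adjusted p = 1.2e-10, and adjusted p = 0.113 with an estimated correlation), with HSP101 down by 0.95 (log2 change -0.95, SE 0.19). Jasmonate and ethylene defence genes were lower (0 of 7 rose, 2 fell; adjusted over the list alone, 0 and 4; median -1.64; camera adjusted p = 4.54e-06, and adjusted p = 0.107 with an estimated correlation), and the ethylene response factor gene ORA59 fell by 2.04 on the log2 scale (SE 0.33). Root markers were lower (0 of 9 rose, 4 fell; adjusted over the list alone, 1 and 4; camera adjusted p = 4.78e-05, and adjusted p = 0.19 with an estimated correlation), and PRP3 fell by 2.55 on the log2 scale (SE 0.33). Expansins and XTHs went both ways (2 of 22 rose, 8 fell; adjusted over the list alone, 3 and 10; camera adjusted p = 0.0111, and adjusted p = 0.283 with an estimated correlation). XTH24 fell by 1.54 on the log2 scale (SE 0.23) while EXPA15 rose by 1.35 (SE 0.17). The expansin call was lost without grf123 replicate 1 (camera adjusted p = 0.0523). Counts falling without grf123 replicate 3 were 1 for touch, heat shock and root markers and 2 for expansins. Touch had 2 falling without grf123 replicate 1 or 2 and a median of -0.73 without WT replicate 3. Heat shock had 3 falling without WT replicate 1, 2 or 3, expansins 5 without WT replicate 2, and 1 root marker rose without grf123 replicate 1. The touch and wound, heat shock, root marker and abscisic acid lists were called lower in both overexpressors too, and the iron deficiency list higher. These directions are thus not particular to a genotype. They may come in part from the WT libraries that all comparisons share, which was tested only by leaving out single libraries. Without WT replicate 3 the touch and wound median moved toward 0 or past it in each genotype. It went from -0.83 to -0.41 in GRF1_OE, where the call was lost (camera adjusted p = 0.0863), and from -0.35 to 0.05 in GRF3_OE. In the libraries labelled grf123 it went from -1.24 to -0.73. For this list the shared direction thus rests in part on that library. The medians of the other lists named here kept their sign without it.

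The oxidative stress list, which holds CSD1, CSD2, CCS and FSD1, had 3 of 17 members rising and 1 falling (adjusted over the list alone, 5 and 2), a median of -0.01, a mean of 0.30 and an upward test (camera adjusted p = 0.00247, and adjusted p = 0.232 with an estimated correlation). Its median lay between -0.12 (without grf123 replicate 3) and 0.20 (without WT replicate 3). It was not called with no filter on low counts (camera adjusted p = 0.132). Meristem genes were called higher on 1 of 5, the growth regulator gene ANT (likewise adjusted over the list alone; camera adjusted p = 0.00812, and adjusted p = 0.113 with an estimated correlation; 0.0533 by camera with no filter). ANT rose by 0.77 (SE 0.16, edgeR adjusted p = 0.00513), and without WT replicate 2 its change of 0.60 did not pass (edgeR adjusted p = 0.0716), which left 0 of the list. The flowering gene FT fell by 2.14 on the log2 scale (SE 0.43, edgeR adjusted p = 0.00903), and the call was lost without grf123 replicate 3 (edgeR adjusted p = 0.121). Iron deficiency (2 of 19 rose, 0 fell; camera adjusted p = 7.72e-05) and photosynthesis genes (2 of 33 rose, 0 fell; camera adjusted p = 0.000604) were called higher. Abscisic acid (2 of 29 rose, 6 fell; camera adjusted p = 0.000865), jasmonate synthesis (2 of 18 rose, 3 fell; camera adjusted p = 0.0071) and nitrate genes (0 of 12 rose, 2 fell; camera adjusted p = 0.0107) were called lower. Adjusted over the list alone, 2 and 0, 2 and 0, 5 and 11, 2 and 6, and 0 and 2 rose and fell. With an estimated correlation the adjusted p = 0.349, 0.516, 0.457, 0.462 and 0.421 for these lists. The iron (camera adjusted p = 0.249), abscisic acid (0.764) and jasmonate synthesis (0.107) calls were lost without grf123 replicate 1, and the jasmonate synthesis (0.199) and nitrate (0.239) calls without WT replicate 3. Counts of these 5 lists moved without single libraries. Iron had 1 rising without grf123 replicate 1 or WT replicate 1 or 2. Photosynthesis had 0 rising without grf123 replicate 2 or 3 or WT replicate 2 or 3, and 4 without grf123 replicate 1. Abscisic acid had 7 rising and 4 falling without grf123 replicate 1, 2 and 3 without grf123 replicate 2, 1 and 3 without grf123 replicate 3, and 1 and 4 without WT replicate 2. Jasmonate synthesis had 0 rising and 1 falling without grf123 replicate 2 or 3, 1 and 2 without grf123 replicate 1, 1 and 3 without WT replicate 2, and 0 and 2 without WT replicate 3. Nitrate had 0 falling without grf123 replicate 2 or WT replicate 3, and 1 without grf123 replicate 3 or WT replicate 2. Of 29 lists, 15 were called, 5 higher and 10 lower, and 0 by camera with an estimated correlation, where 7 had an unadjusted p under 0.05.

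The overexpressors were then compared directly, without WT. The 8 largest increases in GRF1_OE over GRF3_OE included ELF4 and FKF1 of the fixed clock list, with GRF1, COR27, JMJD5, COL9, GRP7 and BBX8. COR27 was 16.2 against 1.46 CPM (log2 change 3.46, SE 0.24, n = 3), JMJD5 differed by 3.17 (SE 0.24), ELF4 by 2.37 (SE 0.17), FKF1 by 1.53 (SE 0.17), GRP7 by 1.48 (SE 0.13) and TOC1 by 1.2 (SE 0.11). Lower in GRF1_OE were BAM5 at 19.5 against 91.2 CPM (log2 change -2.24, SE 0.20), NAS3 at 1.97 against 9.15 CPM (log2 change -2.24, SE 0.30) and HEMA1 at 126 against 249 CPM (log2 change -0.98, SE 0.12). GRF1 itself differed by 4.08 (SE 0.16) and GRF3 by -2.96 (SE 0.14). By edgeR's test 204 genes differed, 87 higher and 117 lower in GRF1_OE, while upper-quartile factors gave 106 higher and 101 lower. This count was 124 without GRF1_OE replicate 1, 106 without GRF1_OE replicate 2, 130 without GRF3_OE replicate 1 and 113 without GRF3_OE replicate 3, and 408 in a fit of these 6 libraries alone.

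Phosphate starvation genes were lower in GRF1_OE than in GRF3_OE, with 0 of 15 higher and 6 lower (adjusted over the list alone, 0 and 12) and a median of -0.78 (camera adjusted p = 1.1e-14, and adjusted p = 0.0497 with an estimated correlation). PAP17, an acid phosphatase gene, differed by -0.82 (SE 0.12). Clock genes (7 of 21 higher, 2 lower; adjusted over the list alone, 10 and 7; median -0.02, mean 0.26, test upward; camera adjusted p = 2.78e-07) and expansins and XTHs (0 of 22 higher, 1 lower; adjusted over the list alone, 0 and 3; camera adjusted p = 1.51e-07) were also called with an estimated correlation, each with adjusted p = 0.0497. XTH18 differed by -1.13 (SE 0.21). Chlorophyll synthesis genes (0 of 17 higher, 3 lower; adjusted over the list alone, 0 and 4; camera adjusted p = 4.65e-07, and adjusted p = 0.263 with an estimated correlation) and heat shock genes (0 of 21 higher, 0 lower; adjusted over the list alone, 1 and 7; camera adjusted p = 2.78e-07, and adjusted p = 0.274 with an estimated correlation) were lower. Iron deficiency genes were called higher (0 of 19 past the threshold, likewise adjusted over the list alone; camera adjusted p = 2.97e-05, and adjusted p = 0.57 with an estimated correlation). Abscisic acid genes (0 of 29 higher, 3 lower; adjusted over the list alone, 4 and 7; camera adjusted p = 0.00089) and photosynthesis genes (0 of 33 higher, 0 lower; adjusted over the list alone, 0 and 3; camera adjusted p = 0.00371) were called lower. So were touch and wound genes (0 of 13 past the threshold; adjusted over the list alone, 0 and 0; camera adjusted p = 0.0419), root markers (0 of 9; adjusted over the list alone, 0 and 1; camera adjusted p = 0.0419) and jasmonate synthesis genes (0 of 18; adjusted over the list alone, 0 and 1; camera adjusted p = 0.0492). With an estimated correlation the adjusted p = 0.621 for each of these 5. Without GRF1_OE replicate 3 all 5 calls were lost (camera adjusted p = 0.0641, 0.226, 0.109, 0.0703 and 0.0703 in that order). Calls were also lost without GRF3_OE replicate 3 for abscisic acid (0.0666) and touch (0.0666), and without GRF3_OE replicate 2 for photosynthesis (0.403), touch (0.22) and jasmonate synthesis (0.457). Without GRF1_OE replicate 2 touch (0.0848) and jasmonate synthesis (0.306) were lost, and without GRF3_OE replicate 1 root markers (0.788) and jasmonate synthesis (0.1). With the length trend removed touch (0.0618), root markers (0.0553) and jasmonate synthesis (0.0678) were not called, nor were root markers with the GC trend removed (0.0532). With no filter on low counts root markers (0.169) and jasmonate synthesis (0.0622) were lost. Without GRF1_OE replicate 2 or GRF3_OE replicate 3, 2 phosphate genes and 1 gene each of the abscisic acid and chlorophyll lists were lower, and without GRF1_OE replicate 1, 3 and 1 of the phosphate and chlorophyll lists. The clock list had 1 lower without GRF1_OE replicate 1 or GRF3_OE replicate 1 or 3 and 0 without GRF1_OE replicate 2. Heat shock had 4 lower without GRF1_OE replicate 1 and 3 without GRF3_OE replicate 2. Expansins had 2 and 3 lower without GRF3_OE replicates 2 and 3, and 1 root marker and 1 jasmonate gene were lower without GRF3_OE replicate 2 and 3, in that order. Of 29 lists 11 were called, 2 higher and 9 lower, with 7 called without GRF1_OE replicate 3 and 3 by camera with an estimated correlation.

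GRF1_OE and GRF3_OE, each against WT, shared 1757 genes changed in the same direction, 832 higher and 925 lower, and 2 genes in opposite directions. Independent lists of 3911 and 2226 genes would share 243 in the same direction and 242 in opposite directions. The genotypes shared 754 genes in the same direction with the length trend removed, 426 higher and 328 lower, and upper-quartile factors gave 967 higher and 836 lower. Across genes, which are not independent replicates, the log2 changes correlated at r = 0.814. The average was 0.553 in 20 simulated sets of unchanged groups with shared, simulated WT libraries. EdgeR called 0 shared genes in those sets, since unchanged genes drawn independently are rarely called. No real WT library entered these sets, so they do not measure how many shared calls come from the shared controls. The covariance was 0.185 against a simulated 0.0337, a difference of 0.152. WT has 3 libraries and was not split, so part of the excess may come from the shared controls. The count was 1015 without GRF3_OE replicate 2, 1056 without GRF3_OE replicate 3, 1067 without WT replicate 2 and 1244 without WT replicate 3. Shared decreases included LEA7, RD29B and GRF2, and shared increases NATA1 and DXPS1, an isoprenoid pathway gene. LEA7, GRF2 and NATA1 were called in the same direction in the libraries labelled grf123 too, so they are not particular to the overexpressors. DXPS1 is given as counts because each WT library held 1, against 18, 17 and 3 in GRF1_OE and 10, 19 and 15 in GRF3_OE, and DESeq2 gave it no adjusted p.

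Genes that moved in opposite directions in an overexpressor and in the libraries labelled grf123 were fewer. For GRF1_OE there were 46 such genes, where independent lists would give 94.3, and 360 in the same direction, where they would give 96.5. For GRF3_OE there were 37 against 54.1, and 156 in the same direction against 54.5. The opposite count for GRF3_OE was 22 with the length trend removed. PAL4, a lignin pathway gene, had log2 changes of -0.91 (SE 0.15) in GRF1_OE, -0.89 (SE 0.15) in GRF3_OE and 1.2 (SE 0.14) in the libraries labelled grf123. The transporter gene ABCB15 had -0.93 (SE 0.17), -1.16 (SE 0.18) and 1.2 (SE 0.15). CER1, a wax synthesis gene, had -0.80 (SE 0.12) in GRF1_OE and 0.91 (SE 0.11) in the libraries labelled grf123. IPS1 and PECP1 had 1.65 and 1.05 in GRF3_OE and -1.72 and -2.26 in the libraries labelled grf123. The log2 changes across genes correlated at r = 0.490 for GRF1_OE and 0.396 for GRF3_OE with the libraries labelled grf123. These lie below the 0.547 and 0.550 of simulated unchanged groups with shared, simulated WT libraries. The simulated groups held no real changes, whose variance enters r, so the lower r does not show less agreement than in unchanged groups. The covariance of log2 changes across genes was 0.113 for GRF1_OE and 0.0737 for GRF3_OE with the libraries labelled grf123, against simulated values of 0.0338 and 0.0339, and part of the same-direction excess may come from the shared controls. The opposite count for GRF1_OE was 29 without grf123 replicate 2, 25 without grf123 replicate 3, 21 without WT replicate 1, 16 without WT replicate 2 and 33 without WT replicate 3. For GRF3_OE it was 24 without GRF3_OE replicate 2, 23 without grf123 replicate 2, 19 without grf123 replicate 3, 11 without WT replicate 1, 13 without WT replicate 2 and 25 without WT replicate 3. In all 3 genotypes against WT, 150 genes changed in the same direction, 65 higher and 85 lower, while upper-quartile factors gave 83 higher and 73 lower. GRF2 was near 0 in all 3 genotypes and GRF1 in GRF3_OE was at the level of the libraries labelled grf123. Whether the transgenic plants carried those mutations was not given in the sources used here.

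Transcript length was related to the change in both overexpressors. Across 17924 genes, which are not independent replicates, the Spearman correlation of log2 change with exonic length was -0.379 in GRF1_OE, -0.400 in GRF3_OE, -0.135 in the libraries labelled grf123 and -0.070 between the overexpressors. The third was -0.029 without grf123 replicate 3, and the last was 0.042 without GRF1_OE replicate 1, -0.113 without GRF1_OE replicate 2 and -0.110 without GRF1_OE replicate 3. Among the lower tertile of length (median 1116 bp), 1067 rose and 291 fell in GRF1_OE, and in the upper tertile (median 2734 bp), 210 rose and 1354 fell. The numbers were 668 and 138, and 103 and 819, in GRF3_OE. Genes with seed storage functions were counted at different levels within groups and are given as counts. CRU3, another cruciferin gene, had 37, 139 and 25 counts in the WT libraries, 1, 43 and 360 in those labelled grf123, 0 in each GRF1_OE library and 0, 1 and 0 in GRF3_OE. SESA5, an albumin gene, had 22, 34 and 13 in WT, 1, 6 and 0 in those labelled grf123, 1, 0 and 1 in GRF1_OE and 1, 1 and 2 in GRF3_OE.

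**Figure D5:**
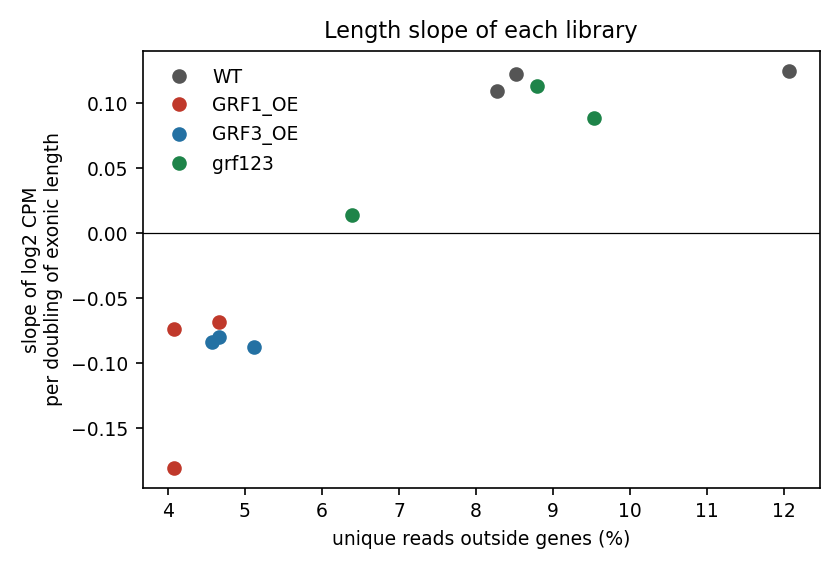
Slope of log2 CPM per doubling of exonic length (y axis) against the share of unique reads outside genes (%, x axis), with a point for each library coloured by labelled genotype. The WT libraries lie at slopes of 0.110 to 0.125 and the overexpressors at -0.181 to -0.0680.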

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

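The clock tests, the tests of a mutant background and of GRF2 repression, and the settings with a length or GC trend removed were chosen only after the result was seen, while what the length tests and the test of another WT seed stock would show was written down before their values were seen; that counting error must be exceeded in the seed stock test, and that splits of 9 libraries say nothing of overlaps, was decided after.

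Reads that overlap more than 1 gene, which enter no gene count, made up a higher share of unique reads in every library of both overexpressors than in any WT library. The lowest shares were 1.78% in GRF1_OE and 1.83% in GRF3_OE, and WT lay at 1.3 to 1.63%. GRF1 and PAP17 were the 2 genes called in opposite directions in the overexpressors against WT. The direct test gave log2 differences of 4.08 (SE 0.16, edgeR adjusted p = 8.61e-14) for GRF1 and -0.82 (SE 0.12, edgeR adjusted p = 0.000192) for PAP17. Against WT, PAP17 changed by -0.34 (SE 0.12, edgeR adjusted p = 0.0488) in GRF1_OE and 0.48 (SE 0.12, edgeR adjusted p = 0.00969) in GRF3_OE. The first call was lost without GRF1_OE replicate 1 or 2, GRF3_OE replicate 1 or 2, grf123 replicate 2 or WT replicate 1, 2 or 3, and over all single libraries left out its edgeR adjusted p was 0.00957 to 0.189. The second was lost without GRF3_OE replicate 3, with a range of 0.00672 to 0.0766.

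Long transcripts were lower, and short ones higher, in both overexpressors than in WT. The trend does not rest on WT replicate 3, since without it the Spearman correlation nearer to 0 of the 2 comparisons was -0.380, nor on GC content, since with the GC trend removed it was -0.350. RNA quality or library preparation, seen as the share of reads outside genes, stays open, since within genotypes that share and the length slope of a library gave Pearson r = 0.440 (exact p = 0.107) and Spearman rho = 0.629 (exact p = 0.0594), both 0.107 after Benjamini-Hochberg adjustment over 2, from 12 libraries and 1296 permutations. Without WT replicate 3 and grf123 replicate 3, whose shares lay farthest from the median after the genotype means were taken off, r was 0.338. The share is confounded with genotype between groups, and an effect of the transgenes on long transcripts stays open as well and was not tested.

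Evening clock genes were higher and morning clock genes lower in GRF1_OE than in WT. The length trend as the whole cause is argued against, since 17 of the 18 called genes kept their call and direction after its removal, with CDF2 moving from -0.76 (SE 0.24) to -0.66 (SE 0.24, edgeR adjusted p = 0.069). WT replicate 3 is argued against too, since 16 of 18 kept them without it, where CDF2 (-0.75, edgeR adjusted p = 0.0604) and CDF1 (-0.34, edgeR adjusted p = 0.118) did not pass. A later hour of collection of the GRF1_OE libraries cannot be told apart from an effect of the genotype, since 0 of 17 called evening and morning genes went against their phase and both predict that. A clock index, the evening minus the morning mean of log2 CPM, was 0.341 ± 0.0773 (SD, n = 3) in GRF1_OE, -1.95 ± 0.448 in WT, -1.23 ± 0.269 in GRF3_OE and -1.72 ± 0.0774 in the libraries labelled grf123.

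GRF2 was near 0 in both overexpressors, and GRF1 in GRF3_OE was below WT. Transgenes carried in plants with the grf1 and grf2 mutations may be a candidate explanation, since GRF1 in GRF3_OE differed from the libraries labelled grf123 by -0.012 on the log2 scale (SE 0.19). Repression of GRF2 by high GRF1 or GRF3 stays open, since the GRF2 difference of -0.30 between GRF1_OE and those libraries (SE 0.52) rests on few counts and both explanations predict a low level. The number of genes that set a genotype at least 4-fold apart from all other libraries was 3 for WT (LEA7, AT2G42560 and GRF2), 9 for GRF1_OE and 2 each for GRF3_OE and the libraries labelled grf123. By the bound written beforehand, a number for WT not above the highest other, WT libraries from another seed stock would be argued against, but 3 and 9 did not differ beyond counting error (exact two-sided binomial p = 0.146, with genes not independent), so this stays open.

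Other splits of the same samples were set beside the counts of calls. With 6 libraries there are 10 splits, too few for a share under 0.05. The real splits gave 3911, 2226, 875 and 204 changed genes for GRF1_OE, GRF3_OE and grf123-labelled libraries against WT and for the overexpressors, where the highest other splits gave 0, 0, 1 and 0. Each other split mixes both genotypes in each group, so their difference enters the spread and holds these counts near 0. The contrast with the real splits thus says little. For gene lists called the real values were 12, 10, 15 and 11 and the highest others 10, 12, 13 and 13, with 1, 5, 1 and 3 of the 10 splits as large. For overlaps, 100 splits of 9 libraries were drawn, the real one included, and 1 in 100 was as large in each case. The 98 splits that parted or mixed the WT libraries call few genes, which holds their overlap at 92, 0 and 2 or less, so these shares say nothing of the overlaps. The real values were 1757 genes in the same direction against a highest other of 1538, 46 in opposite directions for GRF1_OE and grf123-labelled libraries against 0, and 37 for GRF3_OE against 2. The split with 1538 kept the 3 WT libraries together and mixed the overexpressors, so it reflects the difference of both from WT.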

How the results depend on the processing

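The fits with a length or GC trend removed and with ribosomal RNA genes left out were chosen after seeing the data. Counts of changed genes stayed within 1.5 times of their values with RLE or upper-quartile factors, no count filter, a filter of 1 CPM, DESeq2, GC trend or ribosomal RNA genes removed; organelle genes had 0 counts, so leaving them out moved nothing. DESeq2 gave 3102, 1781, 824 and 235 changed genes for GRF1_OE, GRF3_OE and the libraries labelled grf123 against WT and for GRF1_OE against GRF3_OE. With the length trend removed, 2519 genes were called in GRF1_OE (53.3% of the original calls kept) and 963 in GRF3_OE (36.3% kept), 17 lists in GRF3_OE, 754 genes in the same direction and 22 in opposite directions in GRF3_OE and the libraries labelled grf123; the fit takes out any change that follows length. Fits of the 6 compared libraries alone gave 535 genes for the libraries labelled grf123 and 408 for the overexpressors; the cause was not tested. With an estimated correlation camera called 0 lists in each comparison with WT (2, 3 and 7 at an unadjusted p under 0.05) and 3 between the overexpressors.

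Leaving out each library in turn gave 2494 to 3359 changed genes in GRF1_OE, 1200 to 1788 in GRF3_OE, 377 to 1026 in the libraries labelled grf123 and 106 to 181 between the overexpressors. Lists called ranged from 5 to 14 in GRF3_OE and from 7 to 16 between the overexpressors. Genes in the same direction in both overexpressors ranged from 1015 to 1472, and genes in opposite directions from 16 to 65 for GRF1_OE and from 11 to 49 for GRF3_OE with the libraries labelled grf123. These fits have fewer samples and less depth. The fewest grf123-labelled calls came without replicate 3, the deepest library (377); WT replicate 3 had the lowest depth. Named genes were followed over the alternatives apart from no count filter, the filter of 1 CPM and organelle genes left out. They gave 3356 values with the same call, 614 with the call lost and 4 with a call gained. The direction was reversed in 0 values with a call in either fit. The sign of values without a call was not compared.

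With the replicate number as a block, 3710, 2017, 771 and 228 genes and 13, 10, 15 and 11 lists were called, with overlaps of 1616, 39 and 29 genes. Same-numbered libraries correlated at -0.131 to 0.138 after removal of group means, 1 of 18 pairs exceeded 0.1, and 4 of 12 libraries matched best with a library of their own number, so the numbers were not treated as pairs.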

Other observations

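The test of extensin and root hair genes was chosen after the result was seen; the copper and ribosomal protein tests were chosen before theirs, though removal of the length trend was added after the data were seen. GIF1, COPT2 and YSL2 were named after their values were seen.

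GIF1, which encodes a coactivator that binds GRF proteins, was the member past the threshold among 3 measured genes of the coactivator list, too few for the list test. It rose by 1.24 (log2, SE 0.19, edgeR adjusted p = 0.000215) in the libraries labelled grf123 and by 0.81 (SE 0.19, edgeR adjusted p = 0.00446) in GRF1_OE. Over all single libraries left out the edgeR adjusted p was 0.000133 to 0.00611 and 0.00317 to 0.0389. In GRF3_OE the change was 0.62 (SE 0.20, edgeR adjusted p = 0.0417), and the call was lost without GRF1_OE replicate 3, GRF3_OE replicate 1 or WT replicate 2 or 3, with a range of 0.0246 to 0.201, and with the length trend removed (edgeR adjusted p = 0.0778).

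Root hair and extensin genes were among the largest decreases in the libraries labelled grf123, which suggested a hypothesis of lower expression of genes annotated as extensin or root hair specific. Of 71 such genes 43 were measured, 1 rose and 15 fell, with a median log2 change of -0.53 (camera adjusted p = 7.43e-14 over 12 tests; adjusted p = 0.0358 with an estimated correlation). The group holds the genes that prompted it. In GRF1_OE 3 rose and 17 fell with a median of -0.54 (camera adjusted p = 0.0002; adjusted p = 0.212 with an estimated correlation), and in GRF3_OE 3 rose and 4 fell (camera adjusted p = 0.0105; adjusted p = 0.298 with an estimated correlation). A smaller share of root tissue in a whole plant sample would lower these genes too and stays open.

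CSD1, CSD2 and CCS were higher and FSD1 lower in the libraries labelled grf123, the pattern known for plants with more copper, so a lower copper-deficiency response may be a candidate explanation. The 8 copper-deficiency genes had a median log2 change of -0.38, 0 rose and 2 fell (camera adjusted p = 0.000809; adjusted p = 0.0358 with an estimated correlation). COPT2 changed by -0.86 (SE 0.19, edgeR adjusted p = 0.00702) and YSL2 by -1.01 (SE 0.14, edgeR adjusted p = 4.17e-05). In GRF1_OE, where these 8 genes had a median of -0.04 (camera adjusted p = 0.792), CSD1 (log2 change 1.34, SE 0.16, edgeR adjusted p = 7.49e-06) and CSD2 (0.89, SE 0.22, edgeR adjusted p = 0.0139) were higher too. The CSD2 call in GRF1_OE was lost with the length trend removed (edgeR adjusted p = 0.0626) or without WT replicate 1 (0.0515). With 2 of 8 genes past the threshold in the libraries labelled grf123, the explanation stays open.

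Ribosomal protein genes are short, and 78 of 338 rose and 9 fell in GRF1_OE with a median of 0.18 (camera adjusted p = 3.47e-06; adjusted p = 0.298 with an estimated correlation). With the length trend removed 11 rose and 31 fell, with a median of -0.03 and camera adjusted p = 0.258, so a rise beyond the length trend may not be told from these data.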
